A study of Mus musculus with 4 samples.

How the data were processed

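RNA of sorted splenic cells taken up in Trizol was made into libraries with an mRNA-seq kit, per the labels' protocols. Each of the 4 libraries (wt 1, wt 2, ko 1, ko 2) had its own table of gene ID, gene symbol, locus and FPKM, and no read counts. FPKM, the fragments of a gene scaled by transcript length and library size, was computed by the authors before deposit, per the file headers. Bowtie2 2.2.9, TopHat2 2.1.1 and the mm10 build are named, per the submitters' processing notes, with no role or order. The tool that made FPKM from alignments, its annotation, its use of strand and its filters are not given in the sources used here. The tables list only genes above 0. A gene missing from a table was set to 0, which applied to 9 of the tested genes in at least 1 library.

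Genes were matched by ID to GENCODE M21 on GRCm38, the same assembly as mm10, for position, type, transcript length and GC content, and 99.4% of 20735 IDs matched. There were 15518 genes in all 4 tables. FPKM divides by transcript length and by library size, so it hides depth, and it can carry biases of GC content and fragment length from one library to the next. Relative depth was read from steps among values below 0.15 FPKM, where 1 fragment more or less is visible, and put wt 2, ko 1 and ko 2 at 94.3%, 75.5% and 77.1% of wt 1. The absolute scale rests on lengths of single-transcript genes and is approximate. On it, replicate libraries varied by 1.44 to 1.99 times the counting variance, 2.2% to 4.1% per library beyond counting. They were taken as 2 samples per group because the labels list them as separate samples, and this spread does not show that they came from separate mice.

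The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trend of the spread on mean expression, for the 10883 genes with a mean of at least 1 FPKM, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and SE comes from the fit. With 2 libraries against 2 an exact permutation test of one gene cannot go below a two-sided p of 33.3%, so the spread was pooled across genes (prior degrees of freedom 4.4, residual 2). Before the data were examined, 36 gene lists were fixed, of which the 28 with at least 5 tested members went into camera with a preset correlation of 0.01 and adjustment over the lists. None of the camera calls held with an estimated correlation. The estimate lay above the preset for some called lists, as at 0.337 for type I interferon genes. For others it lay below, as at -0.055 for naive and follicular genes, so a higher correlation does not account for their loss. In the simulation described below, with independent genes, camera also passed fewer raised lists with an estimated correlation (80% against 100% at an unadjusted p of 0.05). That setting therefore missed some true shifts there, and a lost call is not evidence that a list did not move. The reason for the loss in the real lists was not tested.

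Named genes followed a rule fixed beforehand: Nsd2; the 10 largest rises and 10 largest falls past the threshold with a mean of at least 5 FPKM and ko libraries beyond both wt libraries, immunoglobulin and T cell receptor segments left out; and from each list up to 4 members with the smallest p, or for other cell types, quality and sex-linked genes up to 3 with the highest FPKM. Genes outside the rule are marked in the report as named after their values were seen, except where a sentence names all members counted. Some members that the rule picks are not reported here by name. On 20 data sets simulated from these libraries, with 200 changed genes each among 10883, the fit called 7.8%, 46.9% and 89.1% of genes changed by 0.2, 0.4 and 0.8 on the log2 scale, and 6.4% of calls fell on unchanged genes. The real fit called 1400 genes. The adjustment is stricter with fewer changed genes, so the shares called may be understated for the real data. Camera passed 0.5% of unchanged lists at an unadjusted p of 0.05 and 100% of lists raised by 0.1, against 80% with an estimated correlation. Genes were simulated as independent of each other, while the real lists had estimated correlations of up to 0.337. These rates for lists may therefore not hold in the real data. Alternatives covered the pseudocount, the filter, scaling between libraries, the variance model, a replicate block, leaving out each library, the thresholds and the list test. Removal of trends on GC content and genomic span was added after the data were seen. Tables were joined with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.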

Results

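Messenger RNA was measured in germinal centre (GC) B cells, the antigen-activated B cells that mutate and select their antibody genes in lymphoid follicles. The cells were sorted from the spleens of 8-week-old C57BL/6 mice immunized with sheep red blood cells, a standard particulate antigen. There were 2 libraries from wild-type (wt) and 2 from Nsd2 knockout (ko) cells. Nsd2 is a methyltransferase that places dimethylation on lysine 36 of histone H3. The files listed 17805, 17731, 17922 and 17827 genes above 0 for wt 1, wt 2, ko 1 and ko 2. Steps among the lowest values put the depth of wt 2, ko 1 and ko 2 at 94.3%, 75.5% and 77.1% of that of wt 1, so the ko libraries were the shallower ones. The labels do not say that the libraries came from separate mice, so p-values may measure only technical spread. Across 10883 tested genes, the log2 values of the libraries differed with an SD of 0.159 within wt, 0.177 within ko and 0.244 to 0.265 between genotypes.

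The question of the study was how GC B cells with and without Nsd2 differ in gene expression. Nsd2 mRNA itself, listed under its older symbol Whsc1 (ENSMUSG00000057406, GRCm38 chromosome 5, 33820725 to 33897975, plus strand), fell by 1.25 ± 0.05 (SE) on the log2 scale in ko. Its level was 76.9 and 81.4 FPKM in the wt libraries and 31.4 and 34.1 FPKM in the ko libraries, a ratio of 0.414 (limma, Benjamini-Hochberg adjusted p = 0.000353, n = 2 per group). The ko libraries therefore still held transcript of the gene, and which part of it was deleted is not given in the sources used here. The files list 2 genes at this locus, so reads of the other one may not be separated from those of Nsd2.

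The heavy chain classes of the B cell receptor moved in opposite directions. The unswitched classes rose, with Ighm at 2688 ± 11.9 FPKM in wt and 3071 ± 52.5 in ko (SD, n = 2) and Ighd at 29.4 ± 0.58 and 37.8 ± 1.4. The switched classes fell. Ighg1 was 656.7 ± 10.8 in wt and 586.7 ± 3.3 in ko, Ighg2b fell by 0.19, Ighg3 by 0.26, Igha by 0.34, Ighg2c by 0.67 and Ighe by 0.79 on the log2 scale. All 8 measured constant genes passed the limma test, and all 8 when adjusted over the list alone, with adjusted p from 0.000898 for Ighg2c to 0.0455 for Igha. Summed as FPKM, the switched classes made up 29.4% ± 0.42 of heavy chain constant signal in wt and 23.9% ± 0.31 in ko (SD, n = 2), a share computed after the values were seen. It is a share of RNA over whole genes and does not give the share of class-switched cells, which was not measured. As a list the constant genes lay lower in ko (camera adjusted p = 0.00716). With an estimated correlation the adjusted p was 0.423. Constant genes of the G classes are similar in sequence, so the split of reads among them is uncertain.

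**Figure D1:**
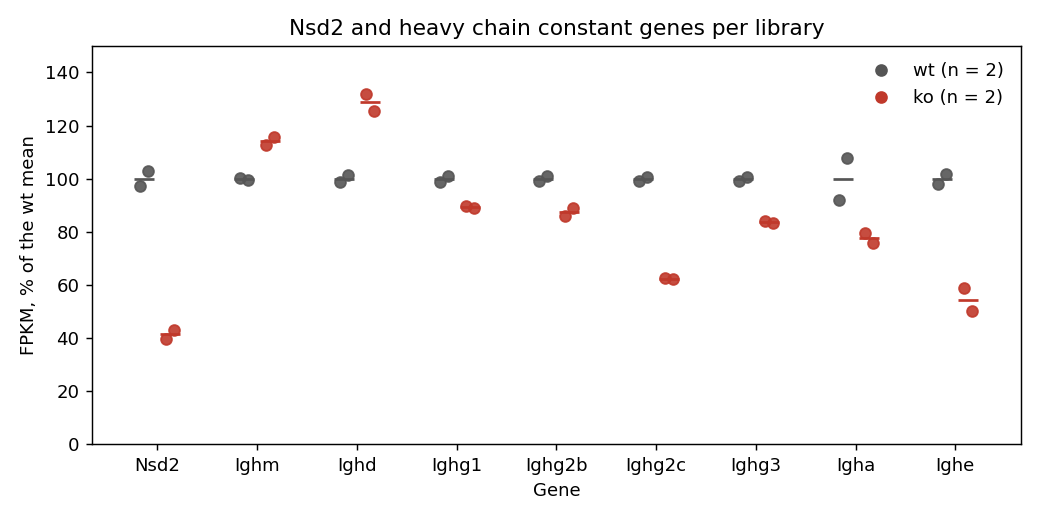
FPKM of Nsd2 and of 8 heavy chain constant genes in each library, as a percentage of the wt mean (y axis). Points are single libraries (n = 2 per group) and horizontal lines are group means. The ko libraries lie below the wt libraries for Nsd2 and the switched classes, and above them for Ighm and Ighd.

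Across the transcriptome, 1400 of 10883 tested genes (12.86%) changed, 725 upward and 675 downward (limma, Benjamini-Hochberg adjusted p below 0.05). Which direction held more genes depended on the settings, with 633 up and 712 down after median-of-ratios scaling and 572 and 647 after quantile normalization. Most changes were small. The median absolute log2 fold change of these genes was 0.31, and 47 rose and 45 fell by at least 2-fold in mean FPKM. In 1397 of them the ko libraries lay beyond both wt libraries. This held for 61.2% of all tested genes, where chance gives 33.3%. The largest rises came from 4 genes with related, repeated sequence, Gm26870, Gm10800, Gm21738 and Gm10718. Gm10800 (ENSMUSG00000075014, chromosome 2, 98666547 to 98667301) was 0.21 ± 0.01 FPKM in wt and 15.6 ± 1.48 in ko (SD, n = 2; adjusted p = 7.9e-05), and the ratios of means of the 4 genes ran from 74.3 to 100.2. That of Gm21738, the highest, rests on wt values of 0.05 and 0.22 FPKM and was 61.7 without wt 1 and 266.2 without wt 2. The genes share sequence, so the split of reads among them is uncertain. The other 6 places among the 10 largest rises with a mean of at least 5 FPKM included Fscn1, an actin-bundling protein. Fscn1 went from 8.98 ± 0.32 to 19.1 ± 0.81 FPKM (log2 fold change 1.01 ± 0.06 SE, adjusted p = 0.00141). The remaining 5 were the transcripts Gm43558, Gm37697, Gm8325, Gm16557 and Gm44206, with log2 fold changes of 0.97 to 1.25. Gm43558 lay at 0.77 without wt 2 and 1.72 without wt 1, and lost its call without ko 1 or ko 2 (adjusted p = 0.0874 and 0.108). Gm44206 lost it without ko 1 or ko 2 (0.104 and 0.0621), and Gm16557 and Gm8325 without wt 1 (0.089 and 0.0616). These 4 and Fscn1 (0.0512) also lost it with no filter on low values, the 4 without the trend of spread on expression, Gm16557 and Gm44206 with the replicate block (0.0536 and 0.0555), and Gm16557 with GC content and span trends removed (0.0625). Gm16557 is a processed pseudogene and Gm8325 a transcribed one, Gm44206 is an antisense gene, and the authors' counting is not stated to use strand.

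Below Nsd2, the largest falls with a mean of at least 5 FPKM were in 9 genes. They were Slc25a13, a mitochondrial aspartate-glutamate carrier, Rsu1, Abcd3, a peroxisomal transporter, Lmo7, Scmh1, a Polycomb-group protein, Ighe, Ggact, Ifit1bl1 and Zdhhc2. Their log2 fold changes ran from -0.92 for Slc25a13 (7.54 ± 0.39 to 3.50 ± 0.26 FPKM, adjusted p = 0.00447) to -0.75 for Zdhhc2 (adjusted p = 0.0109). With no filter on low values all 9 lost their call (adjusted p = 0.078 to 0.0955). Slc25a13 (ENSMUSG00000015112, chromosome 6, 6041218 to 6217173), Rsu1 and Lmo7 each span over 160 kb, a class of 424 genes whose median log2 fold change lay at -0.176 relative to that of genes of up to 10 kb. Rsu1, Abcd3, Ggact and Zdhhc2 share a locus with other genes. Of the 100 genes past the threshold among these 19 largest changes beside Nsd2 and the 4 members of smallest p in each list, 42 to 53 lost their call when 1 library was left out. The count of changed genes fell to 394 without wt 1, 600 without wt 2, 461 without ko 1 and 475 without ko 2. It was 536 without a trend of spread on expression, 14 without a filter on low values, 2540 at an adjusted p below 0.10 and 5 against a minimum log2 change of 0.5.

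**Figure D2:**
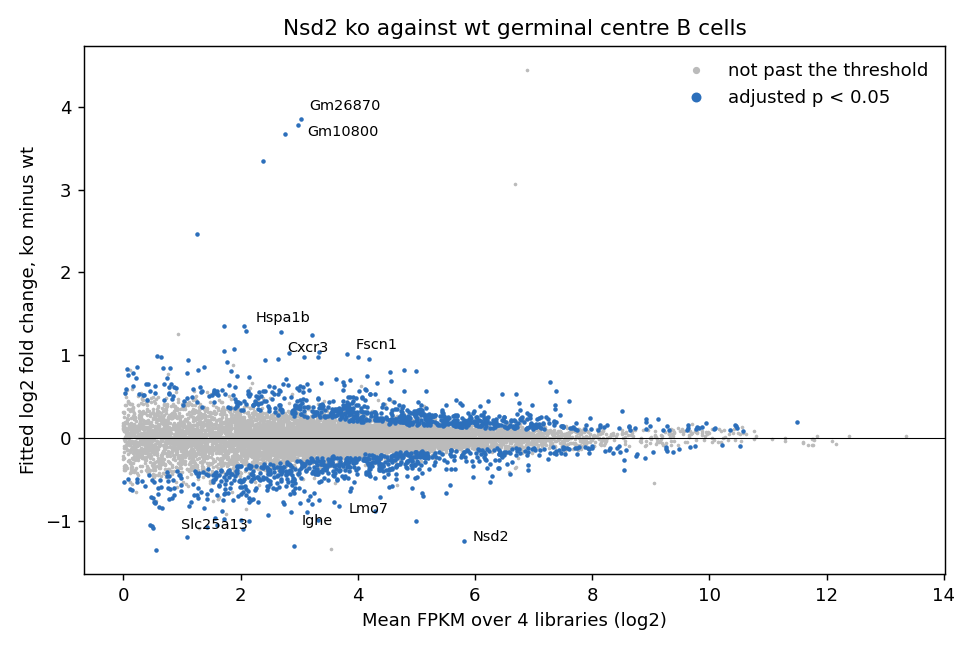
Fitted log2 fold change, ko minus wt (y axis), against the mean FPKM of the 4 libraries on a log2 axis (x axis). Each point is 1 of 10883 genes and blue marks the 1400 past the threshold. Among the blue points 4 genes with related, repeated sequence stand highest, Gm26870, Gm10800, Gm21738 and Gm10718, and Nsd2 is the marked gene at -1.25.

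Genes of naive, follicular and marginal zone B cells, the resting states outside the GC, were higher in ko. Of 19 naive and follicular genes 7 rose and none fell over all genes tested, and 9 rose adjusted over the list alone (camera adjusted p = 0.00368, median log2 fold change 0.19). Among them were Cr2, the complement receptor, from 81.8 ± 1.07 to 98.0 ± 0.81 FPKM, Fcer2a from 68.3 ± 0.22 to 81.4 ± 0.05, Cd38, which mouse GC B cells lower, from 12.6 ± 0.35 to 17.6 ± 0.79, and Ighd. Il4ra and Ccr6, named after their values were seen, rose as well. Of 12 marginal zone and B1 genes 5 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00716). Plac8 rose by 0.53, Cr2 by 0.26 and Tm6sf1 by 0.26 on the log2 scale, while Myof fell by 0.74. With an estimated correlation the adjusted p was 0.297 for both lists. Of 15 memory genes 4 rose and 1 fell, and 5 rose and 1 fell adjusted over the list alone, without the list passing (camera adjusted p = 0.0977). Cxcr3, a chemokine receptor, went from 3.92 ± 0.11 to 8.53 ± 0.49 FPKM (adjusted p = 0.00305) and Vim fell by 0.45 on the log2 scale. Il9r and Cd38 rose. The monocyte and macrophage markers summed to 11.3 and 10.2 FPKM in wt and 15.1 and 15.9 in ko.

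Genes of the GC program went both ways. Of 26 GC identity genes 2 rose and 5 fell, and 4 rose and 10 fell adjusted over the list alone (camera adjusted p = 0.228). Rgs13, a regulator of chemokine signalling, rose from 141.7 ± 0.20 to 187.9 ± 2.54 FPKM, Lmo2 fell by 0.36 on the log2 scale, and Pou2af1 and Neil1 fell by 0.11 and 0.14. Bcl6, the transcription factor that defines GC B cells, was 81.4 and 85.4 FPKM in wt and 81.8 and 85.9 in ko (adjusted p = 0.906, named after its values were seen). Of 15 dark zone genes, those of the dividing and mutating compartment, 1 rose and none fell, and 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0512). Sema4b rose by 0.49 on the log2 scale. Cxcr4, the dark zone chemokine receptor, was 201.2 ± 7.13 in wt and 184.4 ± 4.29 in ko (adjusted p = 0.0593), and Cenpa and Ccnb2 also missed the threshold at adjusted p of 0.0504 and 0.0592. Of 24 light zone genes, those of the compartment where B cells are selected, 7 rose and 1 fell by either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.015). Traf1 rose from 38.5 ± 0.26 to 48.1 ± 0.31 FPKM, Egr3 by 0.49, Batf by 0.32 and Cd86 by 0.17 on the log2 scale. The adjusted p was 0.297 with an estimated correlation. With the trend on GC content removed it was 0.0632 while the median log2 fold change went from 0.08 to 0.09; why the call was lost was not tested. Stress and immediate early genes, a sign of cell handling, rose beside these lists (9 of 21).

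Signalling genes were higher in ko in several lists. Of 24 B cell receptor signalling genes 7 rose and 1 fell, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00231). Cd72 rose from 109.2 ± 3.0 to 133.2 ± 6.5 FPKM, and the kinases Syk, Btk and Blk rose by 0.14 to 0.16 on the log2 scale. The 1 gene that fell was Cd79b, from 634.4 ± 0.28 to 590.1 ± 5.72 FPKM (limma adjusted p = 0.0297). The kinase Lyn, named after its values were seen, did not rise (log2 fold change -0.03, limma adjusted p = 0.525). The list holds both activators and inhibitors of the receptor, and Cd72 is inhibitory. Of 21 NF-kB genes 4 rose, and 5 adjusted over the list alone (camera adjusted p = 0.015). They were Traf1, Ccl22, Nfkbia and Nfkb2, of which Nfkbia encodes an inhibitor of the pathway, and stress and immediate early genes rose beside them. Of 17 MHC class II presentation genes 1 rose, the protease Lgmn by 0.24, and 3 adjusted over the list alone (camera adjusted p = 0.0223). Rfxap, Ctss and Ifi30, with log2 fold changes of 0.31, 0.11 and 0.09, missed the threshold over all genes. Of the 17 genes 12 lay higher in ko and 5 lower. The lower ones were the class II chains H2-Ab1, H2-Aa and H2-Eb1, with Cd74 and H2-DMa, at -0.049 to -0.005 and not past the threshold. Of 16 type I interferon genes 3 rose, Bst2, Irf7 and Ifi27l2a, and 4 adjusted over the list alone (camera adjusted p = 0.0493), with Irf9 at 0.28 and adjusted p = 0.0662 over all genes. Bst2 is also one of the 3 tested dendritic cell markers, all of which rose. Of 13 dendritic cell markers 12 were listed, with a median of 0.0685 FPKM, so most lay near 0. The macrophage markers summed to 11.3 and 10.2 FPKM in wt and 15.1 and 15.9 in ko. Other cells in the sort therefore stay possible for the interferon and MHC class II lists. Of 26 cytokine receptor and adhesion genes 6 rose and 2 fell, and 13 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0154). The integrin chains Itgb2 and Itgal rose by 0.24 and 0.25 and Itga4 fell by 0.34 on the log2 scale. With an estimated correlation the adjusted p of these 5 lists, in the order given, was 0.297, 0.297, 0.557, 0.601 and 0.423. With the GC content trend removed it was 0.0724, 0.153, 0.276, 0.104 and 0.125. The median log2 fold changes went from 0.06 to 0.05 for B cell receptor signalling, from 0.09 to 0.03 for NF-kB, from 0.09 to 0.04 for MHC class II, from 0.17 to 0.13 for interferon and from 0.09 to 0.10 for cytokine receptors, and why the calls were lost was not tested.

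Genes of DNA replication were lower in ko. Of 33 replication and G1/S genes 9 fell and none rose, and 14 fell adjusted over the list alone (camera adjusted p = 6.2e-06, median log2 fold change -0.08). Pcna, the replication clamp, fell from 374.8 ± 0.31 to 333.3 ± 2.3 FPKM, Mcm7 from 164.4 ± 0.64 to 145.0 ± 0.76, and Rrm1 from 146.1 ± 2.5 to 127.0 ± 2.75 (SD, n = 2). Of 29 G2/M genes 2 fell, Cdc25b and Mki67, by either adjustment, including adjusted over the list alone (camera adjusted p = 0.0016). Mki67 was 216.7 ± 0.45 in wt and 199.4 ± 0.91 in ko. Mad2l1 and Ccnb2, at log2 fold changes of -0.13 and -0.12, missed the threshold. Both lists had an adjusted p of 0.297 with an estimated correlation, and with the GC content trend removed the adjusted p was 1.32e-06 for replication and 0.125 for G2/M, whose median log2 fold change went from -0.06 to -0.01. Of 12 cell cycle inhibitors and D cyclins 1 rose and 3 fell, and 3 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.554). Cdk6, Rb1 and Cdkn2c fell by 0.50, 0.35 and 0.22 on the log2 scale, and Ccnd2 rose by 0.31.

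Growth and protein folding genes were higher in ko. Of 29 MYC target and ribosome biogenesis genes 4 rose and none fell, and 10 rose adjusted over the list alone (camera adjusted p = 0.000228). They were Ddx21, an RNA helicase of the nucleolus, from 55.6 ± 0.17 to 63.5 ± 0.17 FPKM, Mrto4, Rrp9 and Tfrc, the transferrin receptor. Of 22 unfolded protein response genes 6 rose by either adjustment, including adjusted over the list alone (camera adjusted p = 0.0016), among them the chaperones Pdia6 (116.6 ± 0.61 to 132.2 ± 1.59), Canx and Calr, and Asns, an amino acid response gene. Heat shock and dissociation stress genes, a sign of cell handling, rose beside them (9 of 21). Of 21 glycolysis genes 4 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0138), with Pfkp up by 0.27, Aldoa by 0.13 and Eno3 by 0.55, and Gapdh down from 1231 ± 1.82 to 1158 ± 9.48 FPKM. With an estimated correlation the adjusted p was 0.297 for MYC targets, 0.423 for the unfolded protein response and 0.441 for glycolysis, and glycolysis lost its call with the GC content trend removed (adjusted p = 0.153, median log2 fold change from 0.11 to 0.07). Oxidative phosphorylation did not move as a list (2 rose and 3 fell of 36, 3 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.953). Its members went both ways, with Ndufb3, Uqcrfs1 and Atp5c1 down by 0.33, 0.15 and 0.11 and Ndufb8 up by 0.23.

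Other lists of chromatin, repair and cell death genes did not pass camera. Among 12 writers and erasers of H3K36 methylation only Nsd2 changed over all genes, while 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.554). Nsd1 was 23.5 and 24.4 FPKM in wt and 26.7 and 27.3 in ko (adjusted p = 0.0532), and Smyd2 and Kdm4a also missed the threshold. With the GC content trend removed 4 of the 12 passed it over all genes, 2 up and 2 down, and the list did not pass (camera adjusted p = 0.376). Of 25 PRC2 and other histone methylation genes 1 rose and 1 fell, Kdm6b and Rbbp7, and Rbbp7 alone passed adjusted over the list alone (camera adjusted p = 0.268). Of 36 genes of hypermutation, class switching and end joining 2 fell, among them H2afx by 0.18, with 0 adjusted over the list alone in limma and a camera adjusted p of 0.159. Of 18 p53 targets 2 rose, Ddit4 and Bbc3, and Polk fell, with 5 up and 3 down adjusted over the list alone (camera adjusted p = 0.554). Of 23 BCL-2 family and caspase genes 1 rose, Bbc3 by 0.48, and 1 fell, with 3 up and 1 down adjusted over the list alone (camera adjusted p = 0.554). Of 21 plasma cell genes Epcam and Fkbp11 rose, both below 3 FPKM on average, and Txndc5 fell by 0.14, with 2 up and 2 down adjusted over the list alone (camera adjusted p = 0.292).

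**Figure D3:**
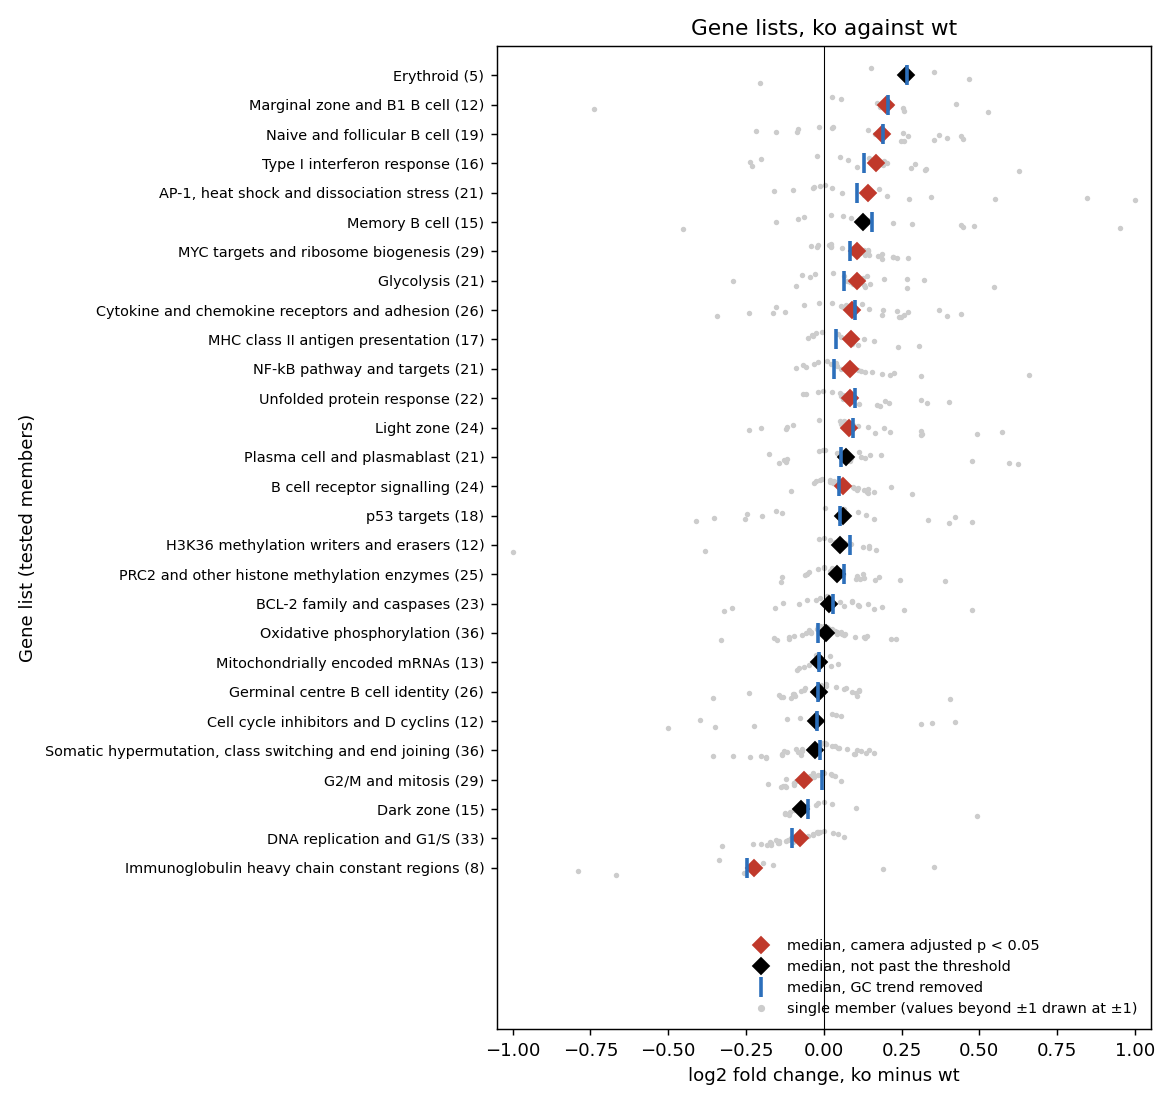
Log2 fold changes, ko minus wt (x axis), for the 28 gene lists tested, with the number of tested members in brackets (y axis). Grey points are members, diamonds list medians (red where camera passed) and blue bars medians after the GC content trend was removed. Heavy chain constant genes and DNA replication lie lowest, at medians of -0.23 and -0.08.

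Markers of cell handling and of other cells moved too. Of 21 genes of AP-1, heat shock and dissociation stress 9 rose, and 13 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00118; adjusted p = 0.297 with an estimated correlation). Of the 3 members with the highest FPKM, Dnaja1 and Hspe1 rose by 0.15 and 0.13 on the log2 scale (adjusted p = 0.0263 and 0.038), and Hspa8 was 1004 ± 11.4 in wt and 1046 ± 8.37 in ko (adjusted p = 0.111). Hspa1b, from 2.07 ± 0.32 to 6.50 ± 0.40 FPKM, and Hspa1a, Nr4a1 and Hsph1, by 0.85, 0.55 and 0.27, also rose, and were named after their values were seen. Hspa1a and Hspa1b are near-identical, so their split is uncertain. Immediate early genes in this list also respond to receptor signalling. Mitochondrial mRNAs, which share reads with nuclear copies, did not pass (0 of 13, 0 adjusted over the list alone, camera adjusted p = 0.175), and the 3 with the highest FPKM were mt-Co1, mt-Atp8 and mt-Co2. T cell markers summed to 91.3 and 89.7 FPKM in wt and 98.2 and 100.9 in ko, mostly from Cd2 and Lck, and none of 4 tested passed by either adjustment, over all genes or adjusted over the list alone. Lyz2, a macrophage gene, rose from 0.47 ± 0.19 to 1.62 ± 0.04 FPKM, the 1 of 3 tested macrophage markers to change, beside Cd68 and Hmox1, and the 1 adjusted over the list alone. The 3 tested dendritic cell markers Ly6d, Flt3 and Bst2 all rose, by 0.28, 0.31 and 0.63, also adjusted over the list alone, and B lineage cells express them as well. Of 5 erythroid genes 0 passed by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.327). The 2 stromal genes, Pecam1 and Mfge8, and the platelet gene Itgb3 did not pass over all genes, but Pecam1 was higher in ko when adjusted over the list alone (limma adjusted p = 0.0353). Itgb3 was the 1 tested gene of its list, so its 0.044 there is an unadjusted p, and 3499 of all tested genes had one below 0.05. The neutrophil markers summed to at most 0.66 FPKM and the NK cell markers to at most 0.92 in any library. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d were expressed in all 4 libraries, between 9.83 and 52.1 FPKM, and Xist was at most 0.01. Of 4 tested sex-linked genes 0 passed over all genes, and Kdm5d was higher in ko adjusted over the list alone (adjusted p = 0.0422).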

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

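The fall of Nsd2 kept its direction and stayed past the threshold under all alternatives run, at -1.15 to -1.31. The count of changed genes, 1400, stayed between 1219 and 1453 with other pseudocounts, a floor of 5 FPKM, other scalings and a robust fit. It moved to 14 with no filter on low values (4152 at an unadjusted p below 0.05), 536 without the trend, 394 to 600 when 1 library was left out (394 without wt 1, 600 without wt 2, 461 without ko 1, 475 without ko 2), 2540 at an adjusted p below 0.10 and 5 against a log2 change of 0.5. Leaving out a library leaves fewer samples, and the lone one is assumed to vary like the other group; the causes of the other shifts were not tested. With GC content trends removed, chosen after seeing the data, 1304 genes passed, 974 of them shared, and 1284 with span trends removed too, 893 shared. The count of lists, 15, moved to 7 with the GC content trend removed and to 0 with an estimated correlation (2 at an unadjusted p below 0.05). The list test fry called 14, of which 11 were among the 15, and the other settings called 10 to 18. Under fry the MHC class II, glycolysis, unfolded protein response and interferon lists lost their call (fry adjusted p = 0.0757, 0.0757, 0.0582 and 0.23). The memory, plasma cell and hypermutation lists passed it (fry adjusted p = 0.0269, 0.0379 and 0.0379). Of 100 genes past the threshold among the largest changes and the 4 members of smallest p in each list, 94 lost their call without the filter, 58 without the trend, 51 without wt 1, 42 without wt 2, 53 without ko 1, 49 without ko 2, 18 with the replicate block, 17 with the GC content trend removed and 20 with span trends removed too. Among the 140 genes followed for this, and among the lists, none past the threshold reversed. Other genes past the threshold were not checked for reversal. More genes fell than rose with median-of-ratios scaling (633 up, 712 down), quantile normalization (572, 647), without the trend (231, 305), without ko 1 (219, 242) and without ko 2 (210, 265), unlike the 725 up and 675 down. Tests on read counts were planned only for files with counts and were not run.

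The replicate numbers pair nothing that the labels name, and the deviations of same-numbered libraries had a correlation of -0.08 across genes. With the number as a replicate block 917 genes passed, 867 of them shared with the 1400. The other 2 splits of the 4 libraries gave 0 genes each (91 and 95 at an unadjusted p below 0.05, limma). Both put 1 wt and 1 ko library in each group, so the genotype difference adds to the spread and lowers the calls. Their counts are thus no baseline for the 1400, and 3 splits are too few for a share under 0.05. In data simulated from these libraries, 2 per group, 7.8% of changes of 0.2 on the log2 scale were called, and the parts of depth, spread and library number were not separated. That simulation changed 200 genes, against 1400 called here. The adjustment is stricter with fewer changed genes, so 7.8% may understate the share called in the real data.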

Other observations

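The tests of genomic span, satellites, naive genes and the Nsd2 neighbourhood, the comparison of segment spread and the genes named in this part were chosen after the results had been seen. Of 212 tested immunoglobulin variable segments, pseudogenes included, which mark B cell clones, 68 were past the threshold (limma adjusted p below 0.05), 42 up and 26 down, beside 1400 of all 10883 genes. Among segments of at least 100 FPKM, Ighv1-80 rose from 120.8 and 118.8 FPKM in wt to 188.0 and 197.3 in ko (adjusted p = 0.00069), Igkv16-104 rose by 0.57 on the log2 scale, and Igkv14-111 fell from 423.2 and 421.4 to 324.9 and 323.5 (adjusted p = 0.00131). Segments are similar in sequence, so single values are uncertain. Over 174 variable segments of at least 5 FPKM the median absolute log2 difference was 0.11 within wt, 0.13 within ko and 0.20 to 0.22 between genotypes, against 0.05, 0.06 and 0.09 to 0.10 for 7852 other genes. Malat1, a nuclear noncoding RNA, was 28.7 and 28.8 FPKM in wt and 42.4 and 43.6 in ko (log2 fold change 0.56 ± 0.04 SE, adjusted p = 0.00207).

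Protein-coding genes with a long genomic span were lower in ko. The median log2 fold change of 424 genes over 160 kb lay at -0.176 relative to 2373 genes of up to 10 kb (95% bootstrap interval -0.196 to -0.157), from -0.161 to -0.197 in the 4 pairs of a ko with a wt library, against 0.014 and -0.022 within genotypes. Fold changes also followed GC content (Spearman 0.34 across genes, which are not independent), but with that trend removed the difference stayed at -0.13 (-0.157 to -0.109), and with transcript length and GC content in one model the slope on log2 span was -0.0335, so neither accounts for all of it. More unspliced RNA in wt would need a negative median for transcripts inside introns. The 54 tested transcripts annotated inside protein-coding genes on the same strand had a median log2 fold change of 0.098 (0.017 to 0.146). They were not required to lie clear of exons or in long genes, so this explanation stays open. An effect of Nsd2 loss on transcription of long genes may be the cause, as a hypothesis, but a difference in library preparation between genotypes cannot be told apart from it, since each genotype has its own libraries.

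Satellite-like transcripts were near 0 in wt and present in ko. The 12 listed genes that share at least 5% of their 31-base words with Gm10800 lie on chromosomes 2, 9 and 14, 9 of them with a repeat period of 234 bases, and summed to 0.63 and 0.77 FPKM in wt and 63.8 and 56.1 in ko. Movement of reads between these listed copies would leave the sum alike, and the ratio of sums was 72.7 to 101.4. Movement to or from copies not listed was not tested. Genomic DNA in the ko libraries could also bring satellite sequence. Olfactory and vomeronasal receptor genes, taken as a gauge of DNA, summed to 7.27 and 9.06 FPKM in wt and 7.8 and 10.25 in ko. The ko to wt ratio was 1.11. This cannot be told apart from no DNA, because few fragments would fall there on an assumed satellite content of the genome. Signal already present in wt could also hide them. DNA and transcription of satellites in ko therefore both stay open.

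The rise of naive and follicular B cell genes may reflect a changed GC population or more B cells from outside the GC in the ko sort. The trend on GC content is argued against by a median of 0.19 after its removal, with the list still past the threshold (camera adjusted p = 0.00184). For carried-over B cells, 73.7% of the 19 genes were higher in ko and none was lower past the threshold, which cannot be told apart from a change within GC cells, since the levels of sorted naive cells were not analysed here. Klf2 and S1pr1, also of resting B cells, were 25.5 and 22.2 against 22.3 and 22.6 FPKM and 7.97 and 8.61 against 7.28 and 7.41 in wt and ko. The lower replication genes and higher Ighm and Ighd go with either.

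A passenger effect of the altered locus was tested as a further hypothesis. Of 83 genes within 5 Mb of Nsd2, 14 (16.9%) were past the threshold, against 12.8% of other genes (one-sided Fisher exact p = 0.175, odds ratio 1.38, 95% interval 0.71 to 2.48), which leaves an excess open in either direction.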
